A study of Arabidopsis thaliana with 15 samples.

How the data were processed

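RNA of 15 Arabidopsis thaliana samples in 5 groups of 3 was extracted from about 100 hypocotyl explants each with an RNeasy Plant Mini kit and sequenced from KAPA Stranded mRNA-seq libraries, per the labels. The deposited values are counts, whole numbers of reads per annotated gene for each library, as the authors made them. The labels name FastQC 0.11.7, Bowtie2 2.3.4.3 (an aligner that does not splice), SAMtools 1.9 and bedtools 2.26.0 with the TAIR10 genome build, and they give neither the role nor the order of these tools. Whether duplicates were removed, whether strand was used and whether exons or whole genes were counted is not given in the sources used here. The counts were not normalized for depth. All 15 per-sample columns were mapped to a sample by the library names, and 0 were left over.

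The table held 33602 genes, of which 279 belong to chloroplast or mitochondrion and were at 0 in all libraries. Of the identifiers, 32835 matched the reference annotation, and 100% of these genes overlapped the reference gene, 99.24% started within 1000 bases of it and 32.28% had the same start and end, so coordinates were taken from the table. Total counts ranged from 3427707 to 4446863, a ratio of 1.30, and 22303 to 24396 genes had a count. The highest count was 4757, and the 100 genes with most counts took 3.59% to 4.20% of a library. At this depth 3 counts over a group served as the floor, and counting intervals were at 95%.

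Genes were filtered with filterByExpr, which left 20704, and scaled by TMM, with factors from 0.907 to 1.04. All 15 libraries went into 1 edgeR 4.0.16 quasi-likelihood fit with robust settings in R 4.3.3, and p-values were adjusted by Benjamini and Hochberg per comparison, with a threshold of 0.05 on the adjusted p. The 7 comparisons were 27 °C against 17 °C after CIM and after SIM, the difference between those effects, CIM against 0 h at each temperature and SIM against CIM at each temperature. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation. The 22 lists held 328 genes, 316 of them under the same symbol in the reference. They covered shoot meristem, leaf primordia, root-type callus, wounding, auxin synthesis, auxin response, cytokinin, heat shock, thermomorphogenesis, cold, cell cycle, photosynthesis, flavonoids, jasmonate, salicylate, H2A.Z, the clock, xylem, epidermis, stomata, root hairs and endodermis with suberin. Counts of list genes are over the members that passed the filter, which left 6 of 14 flavonoid, 8 of 14 leaf primordium, 10 of 15 cold and 2 of 10 stomatal genes. Levels are CPM on TMM-scaled library sizes, and log2 fold changes carry their standard error after ±.

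The comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 8 largest changes in each direction for the temperature comparisons, among genes past the threshold with a mean of at least 2 CPM and no overlap between the groups. It takes 5 in each direction for the other comparisons, without the overlap condition for the difference between effects, up to 4 called members with the smallest p per described list, and 14 regeneration genes in every case. After the data were seen, 7 further lists (brassinosteroid, ethylene, gibberellin, Polycomb and DNA methylation, root cap, seed maturation, abscisic acid response) and 4 further alternatives were added. The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, other filters, nuclear genes alone, a replicate block, the compared libraries alone, a threshold of 1 log2 unit, and each library left out in turn. Those added were counts corrected for positions counted once, libraries 1 and 3 of CIM at 27 °C as 1 sample, 0 h library 2 alone, and CIM without library 3 at 17 °C and library 2 at 27 °C. No pairing by library number was seen. Deviations from the group means had correlations from -0.20 to 0.0577 in 30 pairs of equal number and from -0.10 to 0.20 in the others. The spread within several groups was near counting noise, so this does not exclude pairing.

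The methods were tested on simulated data with 20796 genes made from the CIM groups, with 50 changed genes at each fold. edgeR found 50% of the genes at the smallest fold simulated and 76%, 92% and 100% at 1.5, 2 and 4 times, with 8 false calls, and DESeq2 found 28%, then 66%, 86% and 98%, with 0. These shares and false calls hold for the simulated spread between libraries and need not carry over to the data. There, the variance of low-count genes was 1.65 times the mean in the CIM group at the lower temperature and 1.06 times at the higher one. camera found the changed list and called 0 of 21 unchanged lists. The simulated genes varied independently of each other, so this says nothing about false calls in lists whose members are correlated. The correction for positions turned an observed fold of 1.74 into 1.99 for a true fold of 2. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.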

Results

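The series measured messenger RNA by sequencing in hypocotyl explants of Arabidopsis thaliana (Col-0) while hormones in the medium induced shoot regeneration. Explants were cut from 7-day-old seedlings grown in the dark at 22 °C, and about 100 explants made 1 sample. Callus-inducing medium (CIM) held the synthetic auxin 2,4-D at 0.5 mg/L and the cytokinin kinetin at 0.1 mg/L. Shoot-inducing medium (SIM) held the cytokinin 2-iP at 0.5 mg/L and the auxin IAA at 0.15 mg/L. The 15 samples formed 5 groups of 3: explants at 0 h, after 4 days on CIM at 17 °C or 27 °C, and after 4 more days on SIM at 17 °C or 27 °C. Total counts per sample were 3661608 to 3745747 at 0 h, 3427707 to 4105908 after CIM at 17 °C, 3914906 to 4446863 after CIM at 27 °C, 3679115 to 4159645 after SIM at 17 °C and 4140425 to 4319405 after SIM at 27 °C. Levels are given in CPM, counts scaled to a common library size, as the mean ± SD over 3 samples. Libraries 1 and 3 of the CIM group at 27 °C did not differ beyond sampling noise, with 0 genes past a binomial test, so they were taken as 1 sample in these means (n = 2). The 14 other pairs within groups had 1 to 201 such genes, and several pairs after SIM were as close over all counts, so this choice rests on few genes. In the tests, libraries 1 and 3 of this group counted separately. An alternative took them as 1 sample, and there 7 calls of named genes and 1 call of a list were lost. Positions are those of the TAIR10 genome build.

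The first 4 principal components held 52.5%, 27%, 11.5% and 3.86% of the variance. The labels do not say whether the samples of a group came from separate cultures. If they did not, the p-values measure only the spread between these samples, which may be technical. The edgeR fit found little spread beyond counting noise, with a common dispersion of 9.77e-05 and 65.6% of genes at the lowest dispersion. It also pooled unequal groups. In well-expressed genes the variance between libraries was 0.69 times the mean in CIM at 27 °C, 1.09 in CIM at 17 °C and 1.38 at 0 h. The numbers of genes called thus do not show that the changes would recur in separate cultures. In the 0 h group, 18 seed maturation transcripts summed to 5101 counts in library 1, 76 in library 2 and 3575 in library 3. In the group kept on CIM at 17 °C, library 3 held 27 of 29 photosynthesis transcripts at a higher level than both other libraries, with a median log2 ratio of 0.96. Library 2 of the group kept on CIM at 27 °C had a count for 24396 genes, the most of all libraries. The strand of the reads and the handling of reads that fit several places were not stated. Counts of close paralogs (the small heat shock proteins, the LHCB genes, the extensins, VSP1 and VSP2, the GH3 genes, and PLT1 and PLT2) are therefore uncertain in how they divide. Genes nested in a gene on the opposite strand had a median read density 1.12 times that of the outer gene (91 genes). The count of an overlapping gene may thus hold reads of its neighbour. Where a group had 0 counts, a fold change is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its 95% counting interval in brackets. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. If each position was counted once, which stays open, levels and folds of abundant transcripts in all lists would read too low. In the simulation of this, a true fold of 2 read as 1.74.

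After 4 days on CIM, the question was how explants at 27 °C differed from those at 17 °C, before any shoot induction. Genes of cold response, of flavonoid synthesis and of the xylem were lower at 27 °C. AT5G41040, a feruloyl transferase that makes suberin (chromosome 5, 16431374 to 16433305), fell from 49.1 ± 4.23 to 1.95 ± 0.402 CPM, and FAR4 (AT3G44540), a reductase that makes suberin alcohols, fell from 75.5 ± 16.2 to 2.78 ± 0.277 CPM. CHS (AT5G13930), the entry enzyme of flavonoid synthesis, fell from 82.3 ± 10.2 to 31.1 ± 2.61 CPM. YUC4 (AT5G11320), an enzyme of auxin synthesis (chromosome 5, 3611247 to 3613361), rose from 3.99 ± 1.21 to 16.3 ± 1.5 CPM, and the boundary gene CUC2 (AT5G53950) rose from 29.5 ± 6.73 to 49.2 ± 0.401 CPM.

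Of the 10 cold-responsive genes tested after CIM, 8 fell at 27 °C and 0 rose (camera, adjusted p = 2.42e-06). COR6.6 (AT5G15970), a cold-regulated protein, fell from 30.2 ± 1.47 to 3.28 ± 0.418 CPM, and KIN1 (AT5G15960) was at least 18.4-fold lower. Of the 12 xylem and secondary wall markers, 11 fell and 0 rose (camera, adjusted p = 6.31e-06). The lignin laccase LAC4 (AT2G38080) fell from 65.2 ± 3.6 to 35 ± 6.01 CPM and VND7 (AT1G71930), a switch gene for vessel formation, fell from 18.7 ± 1.63 to 7.6 ± 0.909 CPM. Of the 6 flavonoid and anthocyanin genes tested, 5 fell and 0 rose (camera, adjusted p = 1.52e-05), among them FLS1 (AT5G08640) and F3H (AT3G51240), which fell by 1.98 and 2.47 on the log2 scale. With an estimated correlation these 3 lists had an adjusted p of 0.0407, and over the alternatives it was 1.69e-07 to 0.0407 for cold, 5.29e-07 to 0.0407 for xylem and 1.69e-07 to 0.0407 for flavonoid genes. Of the 8 endodermis and suberin markers, 5 fell and 0 rose (camera, adjusted p = 0.00136, and adjusted p = 0.225 with an estimated correlation, in a range of 6.15e-05 to 0.225 over the alternatives).

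No other list passed the camera test after CIM. In the root-type callus and pluripotency list 6 genes rose and 5 fell of 18, with the lateral root regulator LBD29 (AT3G58190) down from 49.6 ± 2.25 to 17 ± 2.25 CPM and WOX11 (AT3G03660), which starts root founder cells, up from 50.9 ± 5.34 to 81.8 ± 2.7 CPM. Among wound-induced reprogramming factors 5 of 11 rose and 0 fell. In that list WIND1 (AT1G78080), a factor that starts callus at wounds, rose by 0.26 ± 0.05 on the log2 scale. In the shoot meristem list 6 of 18 rose and 3 fell. CUC1 (AT3G15170), a boundary gene, rose from 1.56 ± 0.545 to 3.63 ± 0.215 CPM, and LAS (AT1G55580), needed for side shoots, fell from 34.6 ± 2.68 to 19.7 ± 0.418 CPM. Auxin biosynthesis genes divided, with 3 of 8 up and 3 down. Auxin-responsive genes had 2 of 16 up and 8 down. Heat shock genes had 6 of 17 up and 5 down, with the mitochondrial small heat shock protein AT4G25200 up from 0.803 ± 0.737 to 14.7 ± 2.18 CPM and the disaggregase HSP101 (AT1G74310) down from 184 ± 4.62 to 137 ± 6.22 CPM. Photosynthesis and greening genes had 3 of 29 up and 7 down, beside the higher level of these transcripts in library 3 at 17 °C. Circadian clock genes had 4 of 11 up and 5 down, and LHY (AT1G01060), a morning clock gene, fell from 98.8 ± 4.76 to 48.4 ± 2.1 CPM. Counts of genes up and down were 6 and 4 of 15 for cytokinin genes, 4 and 5 of 14 for thermomorphogenesis, 4 and 1 of 8 for leaf primordia, and 6 and 3 of 26 for the cell cycle. They were 1 and 3 of 11 for jasmonate, 3 and 2 of 9 for salicylate, 3 and 0 of 8 for H2A.Z, and 2 and 4 of 8 for the epidermis. For stomata they were 0 and 1 of 2, and for root hairs 1 and 0 of 7. Adjusted over the list alone, up and down counts were the same after CIM except for auxin-responsive (2 and 9), heat shock (6 and 6), photosynthesis (3 and 6), salicylate (4 and 2), H2A.Z (1 and 0), clock (5 and 5) and suberin genes (1 and 5). The median, mean and camera direction differed in sign for the callus, auxin biosynthesis, cytokinin, salicylate and root hair lists. The median of the root hair list was -0.14, or -0.35 with low-count genes at their bound.

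The largest changes after CIM, among genes whose libraries did not overlap (a pattern that chance gives 10% of genes with 3 against 3 libraries, and 20% with 3 against 2 if libraries 1 and 3 at 27 °C are 1 sample), included AT5G51520, an invertase and pectin methylesterase inhibitor family gene that was at least 283-fold lower at 27 °C. MYB39 (AT4G17785), which promotes suberin in the endodermis, was at least 39.8-fold lower, and AT1G65570, a polygalacturonase expressed in the root cap, fell from 119 ± 11.2 to 0.514 ± 0.375 CPM. AT1G23620, AT2G39490 and AT1G24420 were at least 79.9-fold, at least 72.2-fold and at least 43.8-fold lower, and AT4G22640 was lower by 472-fold (84.2 to 18681). AT4G18860 was at least 26.2-fold lower, but its adjusted p was 0.25 with DESeq2, in a range of 1.71e-11 to 0.25 over the alternatives. Among the genes that rose, AT3G13680 was at least 16.9-fold higher, the leaf polarity gene YAB3 (AT4G00180) was higher by 26.8-fold (8.89 to 133), and HB33 (AT1G75240), a zinc finger homeodomain gene, by 109-fold (19.3 to 4360). AT4G02465 and AT5G47600 were higher by 47.1-fold (8.08 to 1894) and 33.9-fold (9.07 to 285). AT1G78750 rose from 0.321 ± 0.367 to 12.1 ± 1.35 CPM, AT5G54560 from 0.531 ± 0.466 to 9.79 ± 0.858 CPM, and MAC5C (AT5G07060) rose by 4.14 ± 0.25 on the log2 scale. PLT5 (AT5G57390), a gene of callus competence, rose by 0.34 ± 0.06 on the log2 scale, whereas WOX5 (AT3G11260) (0.18, edgeR adjusted p = 0.0729), ARR5 (AT3G48100) (-0.15, edgeR adjusted p = 0.125) and ESR1 (AT1G12980) (0.63, edgeR adjusted p = 0.102) did not pass the test. WUS (AT2G17950) had 0 counts in both CIM groups. In all, 8822 of 20704 genes passed edgeR, 4471 higher and 4351 lower at 27 °C, and 2086 of them changed at least 1 log2 unit, 695 up and 1391 down. AIL6 (AT5G10510) rose by 0.17 (edgeR adjusted p = 0.0276) but missed the threshold when library 2 or 3 at 17 °C, or library 1, 2 or 3 at 27 °C, was left out (0.108, 0.186, 0.0945, 0.099 and 0.0698), with libraries 1 and 3 at 27 °C as 1 sample (0.0609), with DESeq2 (0.0581) and without a filter on low counts (0.0663, in a range of 3.42e-04 to 0.383 over the alternatives). CUC1 had an adjusted p of 0.0578 without library 3 at 17 °C and library 2 at 27 °C together, in a range of 0.00379 to 0.0578 over the alternatives.

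After 4 days on SIM, the question was how temperature during culture bears on the shoot program. The labels give a single temperature per sample, so effects of temperature on CIM and on SIM are not separated here. Shoot meristem genes were higher at 27 °C than at 17 °C. WUS, which specifies shoot stem cells (chromosome 2, 7808871 to 7810795), rose from 5.3 ± 0.658 to 14.7 ± 2.41 CPM, and CUC1 (chromosome 3, 5109883 to 5111447) from 5.24 ± 0.99 to 34.3 ± 1.22 CPM. STM (AT1G62360), which keeps meristem cells undifferentiated (chromosome 1, 23058582 to 23061722), was higher by 82.7-fold (14.5 to 3302), at 6.88 ± 0.653 CPM. CYP78A5 (AT1G13710), a cytochrome P450 gene of organ growth, rose from 0.732 ± 0.4 to 41.4 ± 8.24 CPM. Heat shock genes were also higher, and cold, flavonoid, xylem and suberin genes lower.

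**Figure D1:**
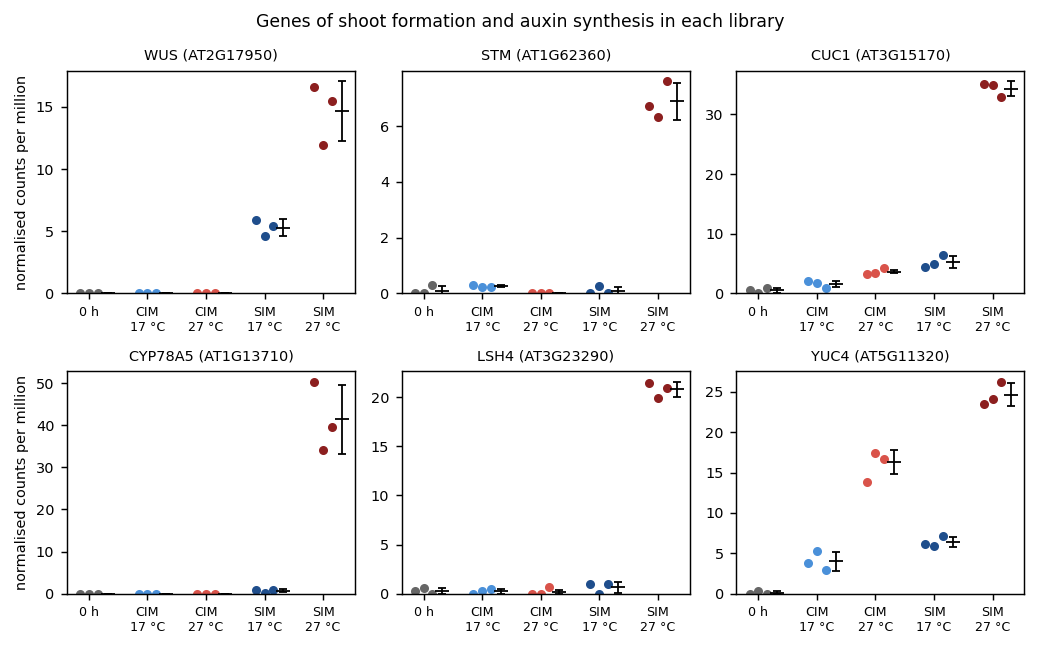
Levels of 6 genes in CPM (y axis) in each library of the 5 groups (x axis), with points for libraries and bars for the mean ± SD. WUS was at 0 after CIM and reached 5.3 CPM after SIM at 17 °C and 14.7 CPM at 27 °C.

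Of the 18 shoot meristem and boundary regulators tested after SIM, 9 rose at 27 °C and 3 fell (camera, adjusted p = 0.00774). LSH4 (AT3G23290), a boundary gene, rose from 0.641 ± 0.556 to 20.8 ± 0.804 CPM, while RAX1 (AT5G23000), a regulator of side meristems, changed by -1.63 ± 0.14 on the log2 scale. Of 17 heat shock proteins and factors, 14 rose and 2 fell (camera, adjusted p = 2.89e-07). HSP90.1 (AT5G52640), a chaperone, rose from 56.1 ± 4.83 to 223 ± 11.7 CPM, and HSP101 (chromosome 1, 27936508 to 27940190) from 55.4 ± 2.67 to 112 ± 1.53 CPM. All 10 cold-responsive genes tested fell (camera, adjusted p = 1.39e-10), with LTI30 (AT3G50970), a dehydrin, down from 109 ± 8.07 to 18.5 ± 2.65 CPM. All 6 flavonoid genes tested fell (camera, adjusted p = 2.51e-07), including MYB12 (AT2G47460), their activator, from 60.3 ± 3.5 to 22.7 ± 3.23 CPM. Of 12 xylem markers 11 fell and 0 rose (camera, adjusted p = 1.003e-04), and all 8 endodermis and suberin markers fell (camera, adjusted p = 3.49e-07). CASP1 (AT2G36100), which forms the Casparian strip, was lower by 96.3-fold (26.3 to 801), and MYB36 (AT5G57620), its activator, fell from 35.6 ± 1.71 to 12.3 ± 0.706 CPM. With an estimated correlation the adjusted p was 0.0127 for cold, 0.0208 for flavonoid, and 0.0312 for shoot meristem, heat shock, xylem and suberin genes. Over the alternatives it was 5.00e-16 to 0.0127 for cold, 5.71e-11 to 0.0208 for flavonoid, 6.46e-04 to 0.0312 for shoot meristem, 6.45e-09 to 0.0312 for heat shock, 7.03e-06 to 0.0312 for xylem and 3.60e-08 to 0.0312 for suberin genes.

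Of 29 photosynthesis and greening genes, 22 rose after SIM at 27 °C and 0 fell (camera, adjusted p = 8.02e-08, and adjusted p = 0.324 with an estimated correlation, in a range of 3.60e-08 to 0.324 over the alternatives). GLK2 (AT5G44190), an activator of chloroplast genes, rose from 2.14 ± 0.491 to 9.87 ± 1.26 CPM, and LHCB4.2 (AT3G08940), a light-harvesting protein, from 8.98 ± 0.445 to 29.4 ± 0.233 CPM. Of 8 epidermis markers, 6 fell and 2 rose (camera, adjusted p = 0.023, and adjusted p = 0.162 with an estimated correlation, in a range of 0.00764 to 0.162 over the alternatives). ATML1 (AT4G21750), a regulator of epidermal identity, fell from 9.27 ± 1.43 to 2.21 ± 0.998 CPM. Of 7 root hair markers, 3 rose and 0 fell (camera, adjusted p = 0.023, and adjusted p = 0.349 with an estimated correlation, in a range of 0.00545 to 0.349 over the alternatives). The list did not pass without library 3 at 17 °C (adjusted p = 0.0752) or library 2 at 27 °C (0.0902), or with corrected counts (0.0606), and its regulator RHD6 (AT1G66470) rose from 12.6 ± 2.72 to 24.6 ± 1.38 CPM. The root-type callus list did not pass the camera test (adjusted p = 0.0696), with 3 of 18 genes up and 9 down. In it the root stem cell gene PLT1 (AT3G20840) fell from 6.67 ± 2 to 0.304 ± 0.124 CPM and SCR (AT3G54220), a ground tissue gene, from 41.2 ± 2.27 to 25.7 ± 1.65 CPM.

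**Figure D2:**
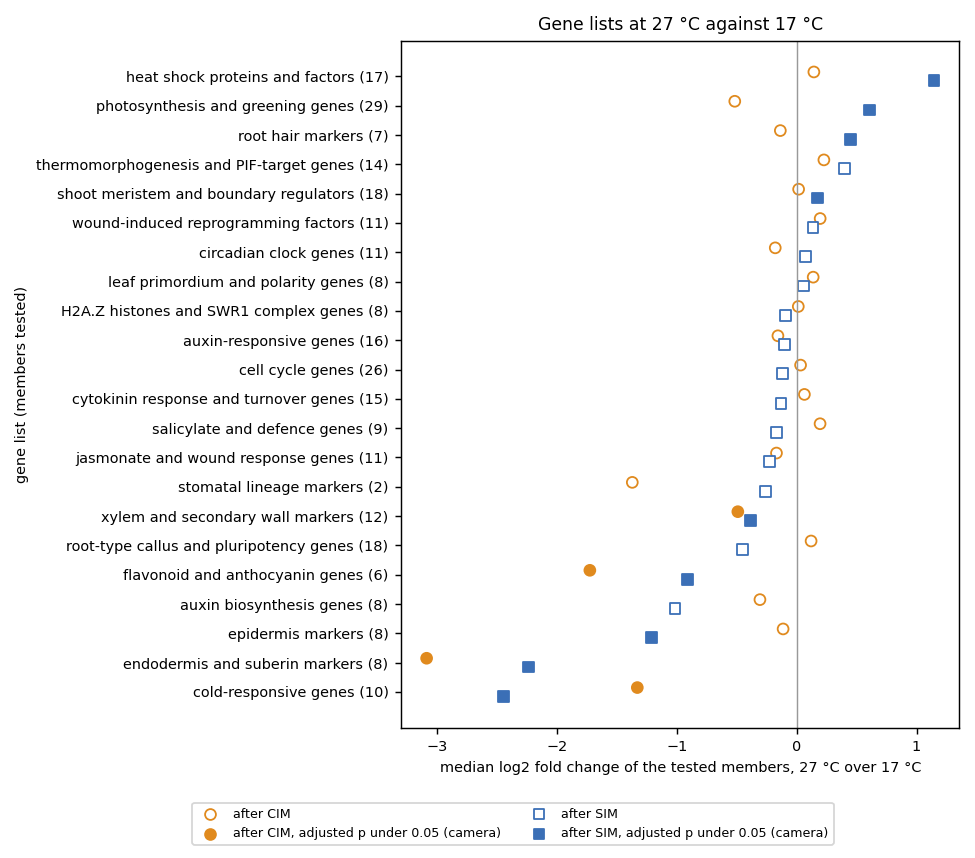
Median log2 fold change (x axis) of 27 °C over 17 °C for each of 22 gene lists (y axis), with circles after CIM and squares after SIM, filled where the camera adjusted p was under 0.05. The heat shock list had a median of 0.14 after CIM and 1.15 after SIM.

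YUC4 rose from 6.4 ± 0.613 to 24.6 ± 1.44 CPM after SIM, and YUC8 (AT4G28720), another enzyme of auxin synthesis, was lower by 22.9-fold (7.47 to 114). Of 8 auxin biosynthesis genes 1 rose and 3 fell. ARR5, a cytokinin response gene, fell from 106 ± 4.12 to 82.7 ± 3.25 CPM, and ARR3 (AT1G59940) from 28.3 ± 2.08 to 6.04 ± 1.01 CPM, within a list with 2 of 15 genes up and 7 down. PIF5 (AT3G59060), a light and temperature signalling factor, rose from 6.01 ± 2.27 to 27.6 ± 2.65 CPM, and HFR1 (AT1G02340), an inhibitor of such factors, fell from 9.3 ± 1.28 to 1.07 ± 0.329 CPM, within a thermomorphogenesis list of 14 genes with 4 up and 4 down. VSP2 (AT5G24770), a jasmonate-induced storage protein, rose from 11.9 ± 0.59 to 80.3 ± 3.4 CPM, and jasmonate genes had 3 of 11 up and 4 down. Genes up and down were 6 and 2 of 11 for wound-induced factors, 4 and 2 of 8 for leaf primordia, and 4 and 5 of 16 for auxin-responsive genes. They were 5 and 6 of 26 for the cell cycle, 2 and 4 of 9 for salicylate, and 1 and 2 of 8 for H2A.Z. For the clock they were 2 and 5 of 11, and for stomata 0 and 0 of 2. No camera test of these lists passed. Adjusted over the list alone, the counts were the same after SIM except for cytokinin (3 up and 7 down), thermomorphogenesis (5 and 5), xylem (0 and 12) and root hair genes (4 and 0). The median, mean and camera direction differed in sign for the auxin-responsive and clock lists. With low-count genes at their bound, the median moved from -1.02 to -0.32 for auxin biosynthesis, from -0.10 to -0.05 for auxin-responsive and from -2.44 to -2.10 for cold-responsive genes.

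The largest changes after SIM, under the same condition of no overlap, included LSH2 (AT3G04510), a gene of the same family as LSH4, higher at 27 °C by 114-fold (31.3 to 949.95), and the mitochondrial small heat shock gene AT4G25200, higher by 59.7-fold (10.3 to 2395). AT5G11930, a glutaredoxin family gene, was at least 30.02-fold higher, and AT1G78750, AT3G28570 and AT1G07440 were higher by 91.9-fold (16.1 to 3666), 74.4-fold (13 to 2976) and 67.1-fold (11.7 to 2686). Among those that fell, AT1G36630 and AT4G06566 were at least 91.8-fold and at least 87.8-fold lower, and AT1G30730, a berberine bridge enzyme family gene, was lower by 395-fold (135 to 1920). GH9B15 (AT4G23560), SBT5.4 (AT5G59810), a subtilase, ELP (AT1G12090) and AT1G35050 were at least 34.8-fold, at least 33.7-fold, at least 31.2-fold and at least 28.7-fold lower, and AT3G48510 was lower by 288-fold (51.3 to 11433). CUC2 rose by 0.57 ± 0.08 on the log2 scale, while ESR1 (0.20, edgeR adjusted p = 0.399) and AIL6 (-0.14, edgeR adjusted p = 0.14) did not pass. ESR2 (AT1G24590) and YUC1 (AT4G32540) had too few counts to be tested, with 25 and 17 counts over the group at 27 °C against 0 and 1 at 17 °C. In all, 9037 genes passed edgeR, 4295 higher and 4742 lower, and 2505 of them changed at least 1 log2 unit, 900 up and 1605 down. WOX5 passed edgeR and was lower by 5.44-fold (1.16 to 51.1), on 10 counts over the group at 17 °C and 2 at 27 °C. However, its adjusted p was 0.0775 with DESeq2, 0.0741 and 0.0895 without library 1 or 2 at 17 °C and 0.131 and 0.124 without library 1 or 3 at 27 °C, in a range of 0.0037 to 0.131 over the alternatives. WIND1 (0.14) lost its call without library 1 or 3 at 17 °C (0.091 and 0.203) or library 1 or 2 at 27 °C (0.0706 and 0.258), with DESeq2 (0.0701) and with the compared libraries alone (0.0604, in a range of 4.82e-04 to 0.258 over the alternatives), and PLT5 (0.20) without library 1 or 3 at 17 °C (0.111 and 0.065) or library 3 at 27 °C (0.0963) and with DESeq2 (0.086, in a range of 0.0129 to 0.111).

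The next question was whether the temperature effect differed between SIM and CIM. The SIM samples were also longer in culture, so this difference does not separate the medium from the length of culture. Heat shock genes gained more from 27 °C after SIM than after CIM. The log2 effect of 27 °C on HSP101 was -0.45 after CIM and 1.01 after SIM, a difference of 1.46 ± 0.08, and for HSP90.1 the difference was 1.83 ± 0.08. STM, with 3 counts after CIM at 17 °C and 0 at 27 °C, was higher at 27 °C after SIM. CUC1 had a difference of 1.45 ± 0.45 in log2 effect, while YUC4 had -0.05 ± 0.27 (edgeR adjusted p = 0.951).

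Of 17 heat shock genes, 10 had a more positive effect after SIM and 0 a more negative one (camera, adjusted p = 1.51e-10, and 0.0392 with an estimated correlation, in a range of 2.78e-13 to 0.0392 over the alternatives). Of 29 photosynthesis genes, 17 were more positive and 0 more negative (camera, adjusted p = 1.44e-09, and adjusted p = 0.333 with an estimated correlation, in a range of 2.13e-13 to 0.333 over the alternatives). Their median of 1.19 was 0.56 without library 3 of CIM at 17 °C, which moves it by over 1.5 times. GLK2 had a difference of 1.88 ± 0.36. Of 18 root-type callus genes, 9 were more negative after SIM and 2 more positive (camera, adjusted p = 0.00192, and adjusted p = 0.199 with an estimated correlation, in a range of 4.54e-04 to 0.199 over the alternatives). PLT1 had a difference of -4.59 ± 0.43 and LBD33 (AT5G06080), a lateral root gene, -3.86 ± 0.38. Of 6 flavonoid genes, 4 were more positive and 1 more negative (camera, adjusted p = 0.0134, and adjusted p = 0.24 with an estimated correlation, in a range of 0.00512 to 0.296 over the alternatives), with CHS at 0.93 ± 0.11 and MYB12 at -1.32 ± 0.15. Without a filter on low counts the median of this list turned from 0.82 to -0.37, with an adjusted p of 0.296. No other list passed. Genes with a more positive and a more negative effect were 5 and 1 in the shoot meristem, 1 and 3 in the leaf, 1 and 4 in the epidermis, 0 and 5 in the cytokinin and 1 and 3 in the cold list. They were 3 and 2 in the suberin, 1 and 0 in the xylem, 0 and 3 in the auxin biosynthesis, 4 and 2 in the auxin-responsive and 2 and 2 in the thermomorphogenesis list. They were 1 and 2 in the wound, 2 and 3 in the jasmonate, 0 and 1 in the salicylate, 1 and 0 in the clock and 0 and 1 in the cell cycle list. For H2A.Z they were 0 and 0, for stomata 1 and 0, and for root hairs 0 and 1. Adjusted over the list alone, more positive and more negative counts differed for photosynthesis (23 and 0), heat shock (11 and 1), callus (2 and 10), leaf (1 and 4), cytokinin (0 and 6), cold (3 and 4), thermomorphogenesis (3 and 2), cell cycle (0 and 0), jasmonate (3 and 4), salicylate (0 and 2) and epidermis genes (2 and 5). The median, mean and camera direction differed in sign for the shoot meristem, wound, jasmonate, clock and root hair lists. With low-count genes at their bound the median moved from -0.09 to -0.03 for shoot meristem, -0.57 to -0.01 for auxin biosynthesis, -0.36 to -0.69 for cold, 1.11 to 1.06 for stomatal and 0.58 to 0.80 for root hair genes.

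**Figure D3:**
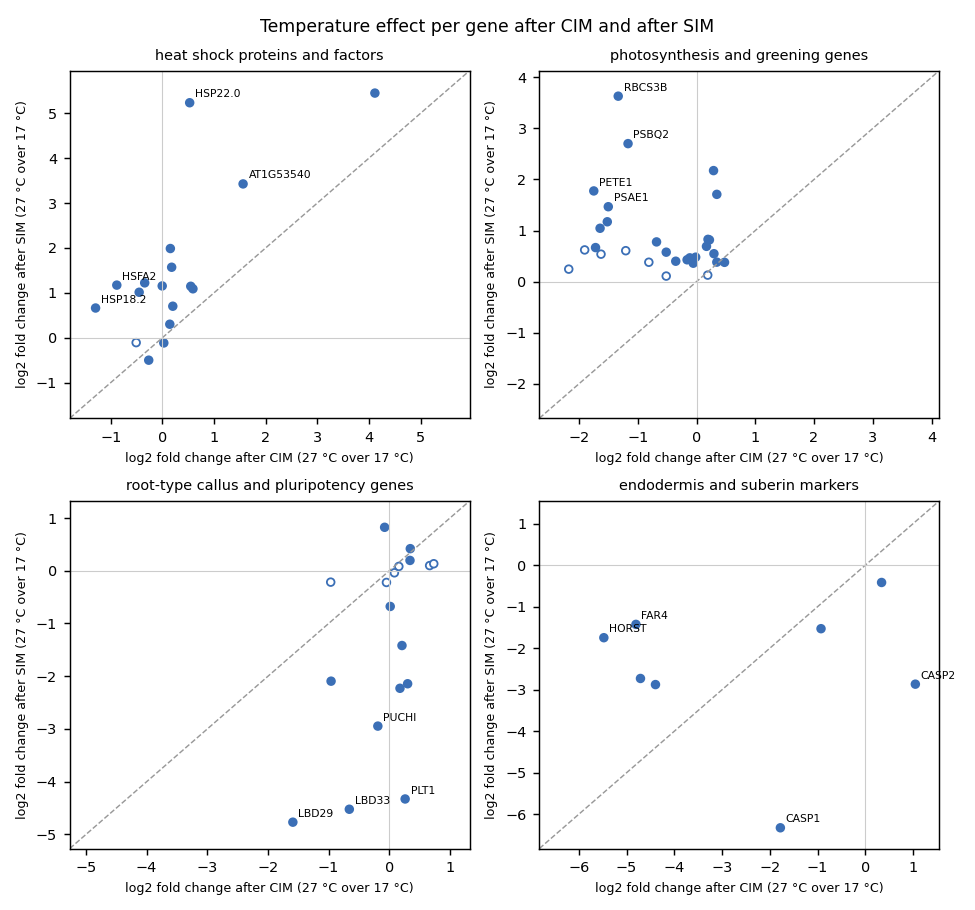
Log2 fold change of 27 °C over 17 °C after CIM (x axis) and after SIM (y axis) for the genes of 4 lists, filled where the edgeR adjusted p after SIM was under 0.05, with a dashed line of equal effect. HSP101 was at -0.45 after CIM and 1.01 after SIM.

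Among single genes with the largest differences between the media, SSL2 (AT2G41290), a strictosidine synthase family gene, fell from 19.6 ± 4.77 to 0.472 ± 0.035 CPM at 27 °C after CIM and rose from 2.03 ± 1.32 to 10.3 ± 2.45 CPM after SIM. AT3G25190, a vacuolar iron transporter family gene, was lower by 42-fold (7.1 to 1702) at 27 °C after CIM and rose from 2.76 ± 0.79 to 27 ± 3.52 CPM after SIM. AT1G34520 was lower by 61.3-fold (16.6 to 513) after CIM and higher by 16.5-fold (2.61 to 689) after SIM. AT3G15830 fell from 13.6 ± 3.17 to 0.36 ± 0.193 CPM after CIM, and AT2G39490 had 0 counts after CIM at 27 °C. AT1G30730 fell from 174 ± 5.73 to 84.1 ± 7.42 CPM after CIM and from 90.8 ± 5.62 to 0.232 ± 0.23 CPM after SIM, and AT3G16660 rose from 2.11 ± 1.01 to 16.9 ± 2.76 CPM after CIM. AT3G48510, AT4G06566 and AT1G36630 had a more negative effect of 27 °C after SIM than after CIM. Of 20704 genes, 3827 passed the test of the difference in edgeR, 1711 more positive after SIM and 2116 more negative, and 1516 of them differed by at least 1 log2 unit, 652 up and 864 down. Of the genes called in both media, 5053 went the same way and 519 opposite ways, 296 of these up after CIM and 223 down. Higher at 27 °C in both were 2469 genes, against 927.5 from independent lists, and lower in both 2584, against 996.5. CUC1 did not pass the difference test without library 1 or 2 of CIM at 17 °C (adjusted p = 0.12 and 0.0785, in a range of 0.00897 to 0.12 over the alternatives). WOX5 (-2.40) and AIL6 (-0.32) passed with all libraries, but WOX5 had an adjusted p of 0.106 and 0.122 without library 1 or 2 of SIM at 17 °C, 0.171 and 0.166 without library 1 or 3 of SIM at 27 °C and 0.0524 without library 3 of CIM at 17 °C and 0.12 with DESeq2, and AIL6 had 0.0615 to 0.11 without library 2 of CIM at 17 °C, any library of CIM at 27 °C, library 2 or 3 of SIM at 17 °C or any library of SIM at 27 °C. AIL6 had 0.0725 without a filter on low counts and 0.0589 with libraries 1 and 3 of CIM at 27 °C as 1 sample. Over the alternatives the adjusted p was 0.00558 to 0.171 for WOX5 and 4.54e-04 to 0.11 for AIL6. The difference given for WOX5 is a fitted value and no bound, since WOX5 had 2 counts over the SIM group at 27 °C.

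The comparison of CIM with 0 h asked what callus induction changed in the explants. Root stem cell and callus genes rose at both temperatures. PLT1 rose from 2.76 ± 1.41 CPM at 0 h to 88.3 ± 6.43 at 17 °C and 106 ± 0.933 at 27 °C, and WOX5, which marks the root stem cell niche, from 5.27 ± 0.8 to 46.5 ± 5.49 and 52.4 ± 1.02 CPM. CUC2 was higher by 293-fold (52.3 to 11622) at 17 °C and 498-fold (89 to 19686) at 27 °C. PIF4 (AT2G43010), a light and temperature signalling factor, was lower by 585-fold (105 to 23157) and 216-fold (73.3 to 1049).

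At 17 °C, 16 of 18 root-type callus genes rose and 0 fell (camera, adjusted p = 6.44e-08), and this list alone passed with an estimated correlation (adjusted p = 0.00793, in a range of 3.00e-11 to 0.00793 over the alternatives). Cell cycle genes rose in 21 of 26 cases and fell in 2 (camera, adjusted p = 2.40e-04, and adjusted p = 0.232 with an estimated correlation, in a range of 1.35e-05 to 0.232 over the alternatives), with the replication gene MCM2 (AT1G44900) up from 50.3 ± 4.03 to 125 ± 9.4 CPM. Heat shock genes rose in 12 of 17 cases and fell in 4 (camera, adjusted p = 0.00456, and adjusted p = 0.257 with an estimated correlation, in a range of 2.75e-04 to 0.257 over the alternatives), and HSP101 rose from 41.6 ± 7.44 to 184 ± 4.62 CPM. Auxin-responsive genes rose in 12 of 16 cases and fell in 3 (camera, adjusted p = 6.71e-04, and adjusted p = 0.257 with an estimated correlation, in a range of 5.34e-06 to 0.257 over the alternatives), with the auxin-conjugating enzyme GH3.1 (AT2G14960) up from 10.9 ± 0.688 to 142 ± 12.3 CPM. Flavonoid genes rose in 5 of 6 cases and fell in 1 (camera, adjusted p = 0.0037, and adjusted p = 0.195 with an estimated correlation, in a range of 3.19e-04 to 0.195 over the alternatives), with CHS higher by 418-fold (115 to 3455). Xylem markers fell in 10 of 12 cases (camera, adjusted p = 4.75e-04, and adjusted p = 0.119 with an estimated correlation, in a range of 8.78e-06 to 0.119 over the alternatives) and jasmonate genes in 7 of 11 (camera, adjusted p = 0.00881, and adjusted p = 0.258 with an estimated correlation, in a range of 0.00149 to 0.258 over the alternatives). LAC4 fell from 209 ± 6.87 to 65.2 ± 3.6 CPM and MYC2 (AT1G32640), the main jasmonate factor, from 255 ± 11.3 to 53.9 ± 3.22 CPM. Clock genes fell in 9 of 11 cases and rose in 2 (camera, adjusted p = 0.0243, and adjusted p = 0.258 with an estimated correlation, in a range of 0.0122 to 0.258 over the alternatives). Thermomorphogenesis genes fell in 8 of 14 and rose in 3 (camera, adjusted p = 0.0436, and adjusted p = 0.231 with an estimated correlation, in a range of 0.00656 to 0.231 over the alternatives). The auxin-responsive list had an adjusted p of 0.0823 with 0 h library 2 alone, the flavonoid list 0.104 and the thermomorphogenesis list 0.0551 without a filter on low counts, and the thermomorphogenesis list 0.0564 with the replicate block.

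At 27 °C, 15 of 18 root-type callus genes rose and 0 fell (camera, adjusted p = 1.35e-06), and all 12 xylem markers fell (camera, adjusted p = 9.43e-06). These lists passed with an estimated correlation as well (adjusted p = 0.0409, in a range of 3.29e-09 to 0.0409 for callus and 3.08e-08 to 0.0409 for xylem over the alternatives). All 8 endodermis and suberin markers fell (camera, adjusted p = 2.85e-04, and adjusted p = 0.175 with an estimated correlation, in a range of 4.23e-05 to 0.175 over the alternatives), with MYB36 down from 49.3 ± 2.55 to 2.36 ± 0.17 CPM. Cold-responsive genes fell in 9 of 10 cases and rose in 1 (camera, adjusted p = 0.00202, and adjusted p = 0.175 with an estimated correlation, in a range of 1.10e-04 to 0.175 over the alternatives), with COR47 (AT1G20440), a dehydrin, down from 258 ± 7.48 to 39.3 ± 0.984 CPM. Cell cycle genes rose in 20 of 26 cases and fell in 2 (camera, adjusted p = 2.09e-04, and adjusted p = 0.217 with an estimated correlation, in a range of 1.87e-05 to 0.217 over the alternatives). Heat shock genes rose in 12 of 17 and fell in 3 (camera, adjusted p = 0.00316, and adjusted p = 0.22 with an estimated correlation, in a range of 1.83e-04 to 0.22 over the alternatives). Auxin-responsive genes rose in 12 of 16 and fell in 4 (camera, adjusted p = 0.00316, and adjusted p = 0.22 with an estimated correlation, in a range of 1.10e-04 to 0.22 over the alternatives). Leaf primordium genes rose in 6 of 8 and fell in 1 (camera, adjusted p = 0.0396, and adjusted p = 0.22 with an estimated correlation, in a range of 0.0141 to 0.22 over the alternatives), with the growth gene GIF1 (AT5G28640) up from 2.37 ± 0.754 to 74.2 ± 7.47 CPM. Jasmonate genes fell in 8 of 11 and rose in 1 (camera, adjusted p = 0.00951, and adjusted p = 0.22 with an estimated correlation, in a range of 0.00107 to 0.22 over the alternatives). Clock genes fell in 9 of 11 and rose in 1 (camera, adjusted p = 0.012, and adjusted p = 0.22 with an estimated correlation, in a range of 0.00582 to 0.22 over the alternatives). Thermomorphogenesis genes fell in 9 of 14 and rose in 3 (camera, adjusted p = 0.038, and adjusted p = 0.175 with an estimated correlation, in a range of 0.0105 to 0.175 over the alternatives). With 0 h library 2 alone the auxin-responsive and leaf lists had an adjusted p of 0.152 and 0.0561, and without a filter on low counts 0.0857 and 0.0798. The thermomorphogenesis list had 0.0501 with CIM libraries 1 and 3 at 27 °C as 1 sample.

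Lists that passed in neither comparison with 0 h, or at 1 temperature alone, had these counts of genes up and down at 17 °C and at 27 °C. They were 9 and 4, then 10 and 4, for shoot meristem, 7 and 3, then 7 and 3, for wound, and 7 and 4, then 7 and 5, for cytokinin genes. They were 2 and 6, then 1 and 6, for auxin biosynthesis, 15 and 6, then 11 and 9, for photosynthesis, and 5 and 4, then 4 and 2, for salicylate genes. They were 5 and 2, then 5 and 2, for H2A.Z, 2 and 5, then 2 and 5, for epidermis, and 1 and 1 at both temperatures for stomatal genes. Root hair markers had 1 and 0 at both. Leaf genes at 17 °C had 4 and 2, cold genes 3 and 7, suberin genes 1 and 5, and flavonoid genes at 27 °C had 4 and 1. Adjusted over the list alone, the counts were the same except for photosynthesis at 27 °C (11 and 8). The median, mean and camera direction differed in sign for the salicylate list at 17 °C. Photosynthesis transcripts summed to 388.7, 400.5 and 687.2 CPM in libraries 1, 2 and 3 of CIM at 17 °C. The 0 h libraries had 513.9 to 559.4 CPM, so library 3 alone was above them. With low-count genes at their bound, medians at 17 °C moved from 0.34 to 0.40 for shoot meristem, 0.76 to 0.02 for leaf, 2.28 to 2.15 for heat shock and 1.43 to 1.36 for root hair genes, and at 27 °C from 0.49 to 0.58 for shoot meristem and 1.79 to 0.51 for root hair genes.

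Among the largest changes from 0 h at 17 °C, AT1G65570 and NAC015 (AT1G33280), a root cap maturation factor, were at least 399-fold and at least 248-fold higher, and AT5G51520 and CSLB03 (AT2G32530), a cellulose synthase-like gene, at least 219.6-fold and at least 212-fold higher. AT5G60530 was higher by 2813-fold (505 to 111150). LTI65 (AT5G52300), an abscisic acid response gene, and KCS19 (AT5G04530), a fatty acid elongase, were at least 848-fold and at least 485-fold lower, and AT3G55230, AT2G10940 and AT5G45950 were at least 464-fold, at least 356-fold and at least 279.8-fold lower. At 27 °C, BRC1 (AT3G18550), a branching repressor, and ELI3-2 (AT4G37990), a defence-induced dehydrogenase, were at least 51.8-fold and at least 58.7-fold higher, AT2G05330 and AT3G16660 were at least 76.3-fold and at least 54.3-fold higher, and AT5G58750 was higher by 761-fold (136 to 30081). MLO3 (AT3G45290), AT2G25150, AT5G19890, AT2G28780 and MYB48 (AT3G46130) were at least 1058-fold, at least 601-fold, at least 503-fold, at least 423-fold and at least 412-fold lower. YUC4 was higher by 40.3-fold (6.89 to 1626) at 17 °C and 161-fold (28.5 to 6378) at 27 °C, and ESR1, a promoter of shoot regeneration, by 15-fold (3.86 to 129) and 23.3-fold (6.17 to 197). AIL6 rose by 2.83 ± 0.10 and 3.01 ± 0.10 on the log2 scale and PLT5 by 1.12 ± 0.08 and 1.46 ± 0.08. WIND1 fell from 232 ± 3.6 to 154 ± 2.89 and 186 ± 6.53 CPM and ARR5 from 92.7 ± 3.31 to 53.4 ± 2.04 and 47.5 ± 2.57 CPM. STM did not pass at 17 °C (edgeR adjusted p = 0.426) or 27 °C (0.233). At 17 °C, 15982 genes passed edgeR, 7803 up and 8179 down, and 6520 changed at least 1 log2 unit, 3266 up and 3254 down. At 27 °C, 16532 passed, 8169 up and 8363 down, and 7239 changed at least 1 log2 unit, 3647 up and 3592 down. CUC1 rose by 1.57 at 17 °C, but had an adjusted p of 0.15 without 0 h library 2 and 0.0744 without CIM library 1, in a range of 0.00441 to 0.15 over the alternatives, and it rose by 2.82 ± 0.48 at 27 °C. Culture, wounding, light and temperature all differed from 0 h at once, and 0 h libraries 1 and 3 held seed transcripts.

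The comparison of SIM with CIM asked what shoot induction changed in the callus. Callus genes fell, and meristem and cytokinin genes rose at both temperatures. WUS, with 0 counts after CIM, was at least 20.9-fold higher after SIM at 17 °C and at least 63.5-fold higher at 27 °C. WOX5 fell from 46.5 ± 5.49 to 0.839 ± 0.31 CPM at 17 °C and was lower by 341-fold (94 to 2821) at 27 °C. EXPA7 (AT1G12560), a root hair expansin, was at least 80.2-fold and at least 132-fold higher.

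At 17 °C, 15 of 18 root-type callus genes fell and 1 rose (camera, adjusted p = 3.03e-12), with LBD16 (AT2G42430), a callus initiation gene, down from 105 ± 3.72 to 8.38 ± 2.41 CPM. All 8 epidermis markers fell (camera, adjusted p = 1.10e-09), with PDF2 (AT4G04890), a regulator of epidermal identity, down from 84.3 ± 2.35 to 15 ± 1.76 CPM. Heat shock genes fell in 12 of 17 cases and rose in 1 (camera, adjusted p = 1.95e-08). Cytokinin genes rose in 12 of 15 cases and fell in 1 (camera, adjusted p = 7.11e-08), with ARR5 up from 53.4 ± 2.04 to 106 ± 4.12 CPM and ARR15 (AT1G74890) from 5.89 ± 0.189 to 47.4 ± 1.66 CPM. Shoot meristem genes rose in 10 of 18 cases and fell in 2 (camera, adjusted p = 0.00285), and flavonoid genes in all 6 (camera, adjusted p = 6.88e-08), with CHS up from 82.3 ± 10.2 to 239 ± 10.3 CPM. Cold-responsive genes rose in 7 of 10 (camera, adjusted p = 2.28e-04), xylem markers in all 12 (camera, adjusted p = 1.45e-04) and root hair markers in all 7 (camera, adjusted p = 7.11e-08). With an estimated correlation these 9 lists passed, at 0.00101 for callus and up to 0.0459 for root hair genes, and over the alternatives their adjusted p was 1.73e-22 to 0.00101 and 2.85e-09 to 0.0459. Photosynthesis genes rose in 20 of 29 cases and fell in 2 (camera, adjusted p = 7.11e-08, and adjusted p = 0.216 with an estimated correlation, in a range of 1.78e-15 to 0.216 over the alternatives), with library 3 of CIM at 17 °C higher in these transcripts. Auxin-responsive genes fell in 10 of 16 cases and rose in 1 (camera, adjusted p = 1.60e-05, and adjusted p = 0.0968 with an estimated correlation, in a range of 6.10e-09 to 0.0968 over the alternatives). Salicylate genes rose in 5 of 9 (camera, adjusted p = 0.0125, and adjusted p = 0.135 with an estimated correlation, in a range of 0.00883 to 0.135 over the alternatives), with the transporter EDS5 (AT4G39030) up from 11.8 ± 1.21 to 56.1 ± 1.23 CPM. Suberin markers rose in 6 of 8 and fell in 1 (camera, adjusted p = 0.00822, and adjusted p = 0.135 with an estimated correlation, in a range of 0.0039 to 0.135 over the alternatives). Both stomatal markers tested fell (camera, adjusted p = 0.0376, and adjusted p = 0.185 with an estimated correlation, in a range of 0.0179 to 0.742 over the alternatives), a call that ended without library 3 of CIM at 17 °C (0.0586), without this library and library 2 of CIM at 27 °C (0.0616), with the replicate block (0.0513) and without a filter on low counts (0.742).

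At 27 °C, 15 of 18 root-type callus genes fell and 0 rose (camera, adjusted p = 2.09e-14), and all 8 epidermis markers fell (camera, adjusted p = 7.60e-10). Shoot meristem genes rose in 13 of 18 cases and fell in 1 (camera, adjusted p = 2.65e-06), with CUC1 up from 3.63 ± 0.215 to 34.3 ± 1.22 CPM and STM at least 29.8-fold higher. Cytokinin genes rose in 12 of 15 and fell in 2 (camera, adjusted p = 4.61e-05), flavonoid genes rose in 5 of 6 (camera, adjusted p = 3.44e-06) and xylem markers in all 12 (camera, adjusted p = 1.49e-05). With an estimated correlation these 6 lists passed, at up to 0.0169 for flavonoid and xylem genes, in a range of 9.42e-10 to 0.0169 and 5.28e-07 to 0.0169 over the alternatives. All 29 photosynthesis genes rose (camera, adjusted p = 2.22e-17, and adjusted p = 0.112 with an estimated correlation, in a range of 5.69e-28 to 0.112 over the alternatives), with LHCA1 (AT3G54890), a light-harvesting protein, up from 11.6 ± 1.2 to 52.3 ± 1.32 CPM. All 7 root hair markers rose (camera, adjusted p = 8.64e-08, and adjusted p = 0.0553 with an estimated correlation, in a range of 9.23e-10 to 0.0553 over the alternatives). Heat shock genes fell in 12 of 17 and rose in 2 (camera, adjusted p = 9.86e-04, and adjusted p = 0.113 with an estimated correlation, in a range of 3.82e-04 to 0.113 over the alternatives). Auxin-responsive genes fell in 10 of 16 and rose in 1 (camera, adjusted p = 2.55e-05, and adjusted p = 0.112 with an estimated correlation, in a range of 2.01e-07 to 0.112 over the alternatives). Suberin markers rose in 5 of 8 (camera, adjusted p = 0.0114, and adjusted p = 0.219 with an estimated correlation, in a range of 0.00308 to 0.219 over the alternatives). Cell cycle genes fell in 12 of 26 and rose in 1 (camera, adjusted p = 0.0212, and adjusted p = 0.326 with an estimated correlation, in a range of 0.00305 to 0.326 over the alternatives). H2A.Z genes fell in 5 of 8 (camera, adjusted p = 0.0318, and adjusted p = 0.231 with an estimated correlation, in a range of 0.00715 to 0.231 over the alternatives). Without library 3 of CIM at 27 °C the cell cycle list had an adjusted p of 0.052, and without library 1 of SIM at 27 °C the H2A.Z list had 0.0637. With corrected counts they had 0.0783 and 0.0668.

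Lists without a call had these counts of genes up and down from CIM to SIM at 17 °C and at 27 °C. They were 4 and 1, then 4 and 3, for leaf, 4 and 2, then 5 and 3, for wound, and 2 and 3, then 2 and 2, for auxin biosynthesis genes. They were 2 and 2, then 5 and 2, for thermomorphogenesis, 4 and 1, then 2 and 2, for jasmonate, and 6 and 3, then 6 and 2, for clock genes. At 17 °C they were 2 and 6 for cell cycle and 0 and 2 for H2A.Z genes, and at 27 °C 5 and 3 for cold, 6 and 0 for salicylate and 0 and 2 for stomatal genes. Adjusted over the list alone, counts differed at 17 °C for auxin-responsive (2 and 10), photosynthesis (22 and 2) and jasmonate genes (4 and 2). They differed at 27 °C for wound (6 and 3), heat shock (3 and 13), thermomorphogenesis (6 and 2), cell cycle (2 and 14) and clock genes (6 and 3). The median, mean and camera direction differed in sign at 27 °C for the leaf, thermomorphogenesis, cold and jasmonate lists. With low-count genes at their bound, medians at 17 °C moved from -3.47 to -1.92 for stomatal and 6.22 to 5.78 for root hair genes, and at 27 °C from 0.54 to 0.08 for cold and -2.35 to -0.86 for stomatal genes.

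Among the largest rises from CIM to SIM, the extensin gene EXT6 (AT2G24980) was at least 526-fold higher at 17 °C and at least 808-fold at 27 °C, and AT5G06630 at least 321-fold and at least 479.9-fold. At 17 °C EXT10 (AT5G06640), EXT12 (AT4G13390) and AT4G08410 were at least 519-fold, at least 348-fold and at least 373-fold higher, and at 27 °C EXT13 (AT5G35190), AT4G08400 and CYP78A5 were at least 268-fold, at least 335-fold and at least 179.7-fold higher. At 17 °C AT2G43860, a pectin lyase family gene, was lower by 524-fold (93.6 to 20724), and AT3G60650, AT1G29025, AT1G29600 and GRP14 (AT5G07510) were at least 38.5-fold, at least 38.5-fold, at least 37.5-fold and at least 30.7-fold lower. At 27 °C AOX1B (AT3G22360), an alternative oxidase, and ASL5 (AT2G30130), a LOB domain gene, were at least 107-fold and at least 75.2-fold lower, and AT4G09940, AT5G48130 and AT1G56680 were at least 192-fold, at least 161-fold and at least 86.6-fold lower. CUC1 rose by 1.75 ± 0.33 at 17 °C, CUC2 by 0.73 ± 0.10 and 0.54 ± 0.08 and ESR1 by 1.97 ± 0.26 and 1.54 ± 0.22 on the log2 scale. ARR5 rose by 0.78 ± 0.06 at 27 °C, and HSP101 fell from 184 ± 4.62 to 55.4 ± 2.67 and from 137 ± 6.22 to 112 ± 1.53 CPM. AIL6 fell from 257 ± 25.6 to 179.6 ± 9.58 and from 291 ± 9.05 to 163 ± 4.56 CPM. WIND1 (edgeR adjusted p = 0.118 and 0.702) and PLT5 (0.87 and 0.125) did not pass at either temperature, nor STM at 17 °C (0.41). At 17 °C, 9955 genes passed edgeR, 5107 up and 4848 down, and 3165 changed at least 1 log2 unit, 1559 up and 1606 down. At 27 °C, 10284 passed, 5154 up and 5130 down, and 3174 changed at least 1 log2 unit, 1600 up and 1574 down. YUC4 rose by 0.63 ± 0.13 at 27 °C and by 0.68 at 17 °C, where its adjusted p was 0.0575 and 0.191 without CIM library 1 or 3 and 0.0907 without SIM library 3 and 0.0606 with DESeq2, in a range of 0.00705 to 0.191 over the alternatives. The SIM samples were also 4 days older than the CIM samples, so medium and time in culture are not separated.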

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

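The tests of seed tissue, of reads from another library, of counting noise and of counts per base in 3 groups, and the correction for positions counted once, were chosen only after the result was seen.

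In the 0 h group, 18 seed maturation transcripts took 0.139% of counts in library 1, 0.0954% in library 3 and 0.00205% in library 2. An abscisic acid response of these explants is argued against by 12 vegetative response genes, whose median log2 ratio of libraries 1 and 3 over library 2 was -0.0876, over a range of -0.32 to 4.00. Reads of another library of the series are argued against as well, since the highest sum elsewhere was 0.0213 of the lower of the 2 sums. Seed tissue or seed RNA in these libraries stays open and may be the source. For 16 of the 17 transcripts with enough counts, or 94.12%, the level in library 2 was under 10% of the mean of libraries 1 and 3. This restates the pattern per transcript and gives no separate support. No biological difference between these samples is named by the design.

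The photosynthesis list had a higher effect of 27 °C after SIM than after CIM, with a difference of 1.19 in median log2 fold change (adjusted p = 0.333 with an estimated correlation). For compression of folds in abundant transcripts, the correction for positions counted once left 109.5% of the median. This test could not decide, since the correction widens folds and the median effect was 0.60 after SIM and -0.52 after CIM. These transcripts summed to 1022 to 1577 CPM in SIM libraries and 388.7 to 687.2 CPM in CIM libraries. Compression would thus narrow the effect after SIM more. Library 3 of CIM at 17 °C, which holds more of these transcripts, could account for part: without it 46.63% of the median was left, at 0.56, with a camera adjusted p of 2.20e-05, in a range of 2.13e-13 to 0.333 over the alternatives. Since library 3 held more of these same transcripts, leaving it out lowers the median by construction and gives no separate support. Without library 1 or 2 of CIM at 17 °C the median was 1.38 or 1.43. Without library 3 of CIM at 17 °C and library 2 of CIM at 27 °C the median was 0.78, with a camera adjusted p of 1.09e-06. An effect of temperature on greening that differs between media or lengths of culture, which are not separated here, stays open.

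In the CIM group at 27 °C and both SIM groups, genes with 100 to 1000 counts varied less between libraries than counting noise, which gives a variance over mean of 1. The highest mean of the 3 groups was 0.6933 ± 0.00765 (SE), while 0 h and CIM at 17 °C had 1.38 and 1.09. Counting noise of plain counts alone would not give so low a value. If positions were counted once, counting noise alone could also fall below 1. The test therefore cannot decide whether these samples differ by counting noise only. Genes with low counts were near 1, at 1.063 in CIM at 27 °C and 1.041 and 1.035 in SIM at 17 °C and 27 °C. Counting each position once stays open and may narrow the spread: variance over mean in the 25% of genes with most counts per base was 64.44% of that in the 25% with fewest in these 3 groups, 70.74% in CIM at 17 °C, 151.1% at 0 h and 82.46% over all groups, the share planned at first. The genes with fewest were still at 0.886 in the 3 groups. Of 26719 protein-coding genes, 6 had more than 1 count per exon base in any library, and the highest value was 2.29. No biological explanation was tested.

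The count of genes whose temperature effect differed between media was 3827. Among 100 splits of the 12 samples drawn at random, 3 gave as many, the real one included. This share decides nothing about chance, since the 85 splits that keep no group whole put the effects of medium and temperature into the spread within groups, and all of them gave 0. The 12 that keep 1 group whole gave 24 to 1945 genes. The highest other split gave 7560 genes and the next 4510, and both keep 2 of the 4 groups whole. For the other 6 comparisons, 10 splits are too few for a share under 0.05. There 1 split, the real one, reached the real count and the highest other gave 0. The real counts were 8822 after CIM and 9037 after SIM for temperature, 15982 and 16532 for CIM against 0 h, and 9955 and 10284 for SIM against CIM, at 17 °C and 27 °C.

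The heat shock list had a median difference between the media of 1.33. The root-type callus list had -0.65 (adjusted p = 0.199 with an estimated correlation, in a range of 4.54e-04 to 0.199 over the alternatives) and the flavonoid list 0.82 (adjusted p = 0.24 with an estimated correlation, in a range of 0.00512 to 0.296 over the alternatives). Without a filter on low counts the flavonoid median turned to -0.37. CUC1 differed by 1.45, HSP101 by 1.46, AIL6 by -0.32 and WOX5 by -2.40 on the log2 scale. The calls of CUC1, AIL6 and WOX5 ended in some alternatives, at an adjusted p of up to 0.12, 0.11 and 0.171. The fitted difference of STM, which had 0 to 3 counts in 3 groups, was 9.11 and is no bound. Fitted values that are no bound either, since a group had 0 to 3 counts, were 9.29 for AT1G34520, 8.65 for AT2G39490, 8.20 for AT3G25190 and 6.83 for AT3G15830. They were -9.74 for AT4G06566, -8.69 for AT1G36630, -7.36 for AT1G30730, -7.26 for AT3G16660 and -7.21 for AT3G48510. SSL2 differed by 7.62. Of 160 genes named for the temperature comparisons, 77 differed between the media.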

How the results depend on the processing

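The corrected counts, libraries 1 and 3 of CIM at 27 °C as 1 sample, 0 h library 2 alone, and CIM without library 3 at 17 °C and library 2 at 27 °C were chosen after seeing the data. Over comparisons and alternatives, 116 counts of genes stayed within 1.5 times, and the 7 others were those with a threshold of 1 log2 unit, which construction lowers: 2086, 2505, 1516, 6520, 7239, 3165 and 3174. The overlap stayed within that range in 18 alternatives and was 1035 with that threshold. DESeq2 gave 7009 and 7231 genes for temperature after CIM and SIM, 2902 for the difference, 15140 and 15726 for CIM against 0 h, and 8427 and 8556 for SIM against CIM. Leaving out 1 library gave 7456 to 8193, 7916 to 8206, 3285 to 3719, 15454 to 15705, 16033 to 16279, 9023 to 9344 and 9310 to 9393 in the same order, and 4518 to 4785 for the overlap. The replicate block gave 8797, 9018, 3793, 15960, 16520, 9903 and 10262. Without library 3 at 17 °C and library 2 at 27 °C, 6907 genes changed after CIM and 3101 differed. 0 h library 2 alone gave 14280 and 14931 genes.

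The number of lists past the test stayed within 1.5 times in 88 cases and not in 7. The difference between effects had 4 lists, 4 to 7 when 1 library was left out, 7 with corrected counts and 1 with an estimated correlation. The estimated correlation left 1 list of 9 for CIM against 0 h at 17 °C, 2 of 11 at 27 °C, 9 of 14 for SIM against CIM at 17 °C and 6 of 13 at 27 °C. List calls kept their side in 778 cases and lost it in 56, of which 36 came with the estimated correlation. In 1 case a median turned, that of flavonoid genes in the difference between effects, from 0.82 to -0.37 without a filter on low counts, past no threshold. Without this filter the flavonoid median also moved from -1.72 to -0.10 for temperature after CIM, from 3.39 to 0 for CIM against 0 h at 17 °C and from 2.68 to 0.16 for SIM against CIM at 27 °C. At 27 °C against 17 °C after SIM the shoot meristem median moved from 0.18 to 0.38, and for SIM against CIM at 27 °C the cytokinin median from 0.61 to 0.22 and the heat shock median from -0.29 to -0.51. Without library 3 of CIM at 17 °C the photosynthesis median for SIM against CIM at 17 °C moved from 1.18 to 1.84, without library 2 the salicylate median from 0.32 to 0.63, and with 0 h library 2 alone the jasmonate median at 27 °C from -1.75 to -1.16. Named genes kept direction and side in 11229 cases, lost the call in 206, gained it in 6 and turned in 13, and each that turned was past no threshold. With 1 library left out, the difference between effects ranged from -0.329 to 0.00332 for CUC2 and from -0.330 to 0.170 for YUC4, which had 0.232 without 2 libraries. The change from CIM to SIM ranged from -0.0490 to 0.0734 for PLT5 at 17 °C and from -0.0886 to 0.0499 for WIND1 at 27 °C. PLT5 had -0.000899 with DESeq2 and -0.0490 without 2 libraries, and WIND1 had 0.00493 without 2. The causes were not tested. Nuclear genes alone moved nothing, since organelle genes were at 0.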

Other observations

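The root cap test and the 7 added lists were chosen only after the result was seen. Since AT1G65570 and NAC015, 2 root cap genes, were among the largest changes, the test left both out. Of 4 other root cap genes 3 were tested, and these 3 were lower at 27 °C than at 17 °C after CIM (camera, adjusted p = 0.00390, and adjusted p = 0.102 with an estimated correlation). SMB (AT1G79580), which matures root cap cells, fell from 19.9 ± 5.44 to 5.54 ± 1.65 CPM, CEL5 (AT1G22880), a cellulase of the root cap, from 119.6 ± 4.98 to 61.9 ± 0.102 CPM, and FEZ (AT1G26870), a factor of root cap stem cells, from 6.55 ± 1.75 to 2.67 ± 0.435 CPM. After SIM 2 of 3 were lower at 27 °C and 0 higher (camera, adjusted p = 0.246). The difference between media had an adjusted p of 0.527, with 1 gene more positive and 1 more negative after SIM.

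Of 12 gibberellin genes tested, 4 rose and 1 fell at 27 °C after CIM, 3 rose and 6 fell after SIM, and 3 had a more positive and 7 a more negative effect after SIM than after CIM (camera, adjusted p = 0.105 for the difference). Of 12 ethylene genes, 4 rose and 2 fell after CIM and 2 rose and 6 fell after SIM. Of 11 brassinosteroid genes 3 rose and 3 fell after CIM, and 3 rose and 4 fell after SIM. Of 14 Polycomb and DNA methylation genes 4 rose and 1 fell after CIM, and 2 rose and 1 fell after SIM. None of these lists passed the camera test in the 3 comparisons, at adjusted p from 0.105 to 0.962. Adjusted over the list alone, counts were the same except for gibberellin genes after SIM, with 3 up and 8 down.

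A hypothesis was that the change from CIM to SIM is further advanced at 27 °C. Of 1991 genes that changed at least 2 times from CIM to SIM at 17 °C and were called for temperature after SIM, 1079, or 54.19%, moved further the same way at 27 °C, against 50.04% for independent lists. Of 1065 that had risen, 434 (40.75%) were higher still at 27 °C and the rest, the larger part, were lower. Of 926 that had fallen, 645 (69.65%) were lower still. Of all genes called for temperature after SIM, 4295 were higher and 4742 lower. Independent lists would give 323.4 and 367.8 genes that moved further. Such values for genes that moved back enter the 50.04% but are not given singly. These excesses alone thus do not favour the hypothesis. The SIM libraries at 17 °C enter both sides. Simulated unchanged genes gave 32.41%, but over 19610 genes not chosen by a 2-fold change or a temperature call, so this is no chance value for the 1991 genes, and the share could not decide.

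Library 2 of CIM at 27 °C had 933 genes with a count in no other library, of which 783 had 1 count, against 42 to 92 such genes elsewhere. It held counts for 754 transposable element genes, against 326 to 422. Genes nested in a gene on the opposite strand had a median read density 1.12 times that of the outer gene (91 genes), and genes nested on the same strand 1.01 times (66 genes). For these nested genes, the values argue against counts kept apart by strand. Libraries 1 and 3 of CIM at 27 °C were the pair among 15 with 0 genes that differed by a binomial test.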
